A study of Homo sapiens with 4 samples.

How the data were processed

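Total RNA from DLD-1 cells was amplified to antisense RNA, coupled to Cy5 and hybridised to single-colour oligonucleotide arrays, per the labels' protocols. The deposited table holds 1 intensity per probe and array on a linear scale for 31741 probes. What the authors did to these intensity values (scanner, background correction, normalization) is not given in the sources used here. The values differ in median between arrays, and 639, 1, 0 and 9 probes are at or below 0 on vector replicates 1 and 2 and HMGA2 replicates 1 and 2. The lowest value on HMGA2 replicate 1 is 62. Summed intensity per array ran from 185042604 to 205024463.

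Groups and replicate numbers were taken from the sample titles: 2 arrays labelled vector and 2 labelled HMGA2. The platform annotation names 1 gene for 24740 probes, several for 977 and none for 6024, and probes with several genes named no gene. Older symbols of 1948 probes were updated through a table of RefSeq genes on assembly GRCh38.p14, which also gave the order and length of genes and the number of protein-coding genes near each; no coordinate from it is printed. Of the symbols, 99.7% were found there. Values below 1 were set to 1 and log2 was taken with no further normalization, as fixed before the data were examined. Each of 18336 genes was represented by its brightest probe, 5455 of them having more than 1 probe, and the 4584 genes below the 25th percentile of mean level were left out, leaving 13752.

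Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes are from limma. HMGA2 probes were also tested in a fit of every probe. An exact permutation of 2 arrays against 2 cannot give a two-sided p below 0.333, so the test borrows its error from all genes. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, two-sided, and members were counted both among all genes and adjusted over the list alone. fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was an alternative.

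The genes named were fixed by rule: HMGA2, then the 12 largest rises and 12 largest falls past the threshold with both arrays of one group above both of the other, then up to 4 members of each list with the largest difference past the threshold. Genes with placeholder names took no place among the 24, and genes of the Y chromosome and XIST were left out.

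The alternatives fixed beforehand were quantile normalization, subtraction of array medians, no filter or a filter at the 50th percentile, the mean of a gene's probes, other variance models, the replicate number as a block, each array left out in turn, every probe as the unit, stricter thresholds, a linear offset, and camera with an estimated correlation. Background correction by normexp with an offset of 50 followed by quantile normalization, and a crossed pairing, were added after the data were seen.

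The test was run on simulated data for 13752 genes with 200 changed genes in each of 10 draws, under a pair of assumptions about the spread. With each gene's own residual SD, 3.73% of genes changed by 0.5 log2, 44.5% of those changed by 1 and 73.9% of those changed by 2 were recovered, and 1.74% of calls fell on unchanged genes. That version came first. Since an SD on 2 degrees of freedom is itself noisy, a second version, added after the result of the first was seen, drew the spread from the prior that limma fitted: it recovered 8.21%, 62.4% and 90.5%, with 3.63% of calls on unchanged genes. With no gene changed the mean number of calls was 0 and 0.2. The simulated noise was independent between genes, with no difference in scaling or background between arrays. These shares of false calls therefore leave out what scaling does to the calls in the data. The cholesterol synthesis list, raised by 0.5 among independent and otherwise unchanged genes, was called in 100% of draws in both. In the data 43.6% of genes passed, so that share does not carry over to lists that did not pass camera. The recovery rates of genes do not carry over either. The adjustment is less strict where so many genes pass than with 200 changed genes, so smaller differences can be called in the data.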

Results

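Gene expression was profiled in DLD-1, an established human colorectal adenocarcinoma line, carrying either an expression plasmid for HMGA2 or the matching plasmid without it. HMGA2 is an AT-hook chromatin protein that is abundant in embryonic tissue and is made again in many tumours. The lines had been selected with 1 mg/mL of the antibiotic G418 and were kept in 0.5 mg/mL. Each line was measured on 2 single-colour arrays, 4 in all, and the comparison asks which transcripts differ between them. Median probe intensity was 698 and 767 on the arrays labelled vector and 649 and 607 on the arrays labelled HMGA2. Across genes, log2 values correlated at r = 0.988 between the vector arrays, 0.992 between the HMGA2 arrays, and 0.957 to 0.958 between arrays of different groups. The number of arrays limits the precision. Nothing in the labels states that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

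HMGA2 itself was not clearly higher on the arrays labelled HMGA2. Its brighter probe read 5423 ± 216 (SD, n = 2) on the arrays labelled vector and 4143 ± 320 on those labelled HMGA2, a log2 difference of -0.39 (SE 0.09, adjusted p = 0.0186). The other HMGA2 probe went the opposite way, from 3110 ± 541 (SD, n = 2) to 4031 ± 799, a log2 difference of 0.37 (SE 0.14, adjusted p = 0.0385 in a fit of all probes). After quantile normalization the differences were -0.19 (adjusted p = 0.115) and 0.59 (adjusted p = 0.0583), neither past the threshold. Where these probes lie relative to the coding part carried by the plasmid is not given in the sources used here, so they may not detect it. The groups are therefore called the arrays labelled HMGA2 and the arrays labelled vector throughout, and each direction given for a gene rests on those labels.

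The largest rises on the arrays labelled HMGA2 included genes of metabolism, motility and signalling. QPRT, an enzyme of NAD synthesis from tryptophan, rose 17.6-fold, from 1462 ± 58.0 to 25739 ± 1028 (SD, n = 2; log2 4.14, SE 0.08, adjusted p = 3.69e-05). S100A4, a calcium-binding protein linked to cell motility, rose 10.1-fold, from 3990 ± 161 to 40240 ± 2336 (log2 3.33, SE 0.08, adjusted p = 4.31e-05). MYLK, the myosin light chain kinase, rose by 3.21 log2, and PRKCQ, protein kinase C theta, by 2.86. The siderophore-binding protein LCN2 rose by 2.45, the glucose transporter SLC2A3 by 2.30 and the scaffold protein IQGAP2 by 2.31. The remaining rises among the 12 largest were PCOLCE2 (2.77), PDE2A (2.70), PIK3AP1 (2.26), GLMP (2.20) and the neurotrophin gene BDNF (3.08). The BDNF value rests on 1 of its 4 probes, since the others gave 0.04, 0.62 and 0.70 and did not pass.

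Falls were larger than rises and reached epithelial and receptor genes. The receptor tyrosine kinase KIT fell 15.9-fold, from 49327 ± 673 to 3109 ± 262 (SD, n = 2; log2 -3.99, SE 0.09, adjusted p = 3.69e-05). CFTR, the chloride channel of epithelia, went from 5972 ± 166 to 356 ± 18.4 (log2 -4.07, SE 0.10, adjusted p = 4.31e-05). PBDC1 went from 14371 ± 1268 to 544 ± 39.6 (log2 -4.72, SE 0.11, adjusted p = 3.69e-05). ZNF711, a zinc finger gene on the X chromosome, also fell (log2 -5.26, SE 0.41, adjusted p = 0.000345), and its other probe gave -3.85. NPNT and COL4A1, both of the extracellular matrix, fell, with log2 differences of -4.57 and -3.26. Second probes gave smaller differences in the same direction, past the threshold, for NPNT (-1.47, SE 0.49), IMPACT (-1.27), REG4 (-2.14), RAB8B (-2.44), MYLK (1.84) and PRKCQ (2.00). The others were NPTX2 (-4.03), SH3BGRL (-3.90), TMT1A (-3.70), the secreted lectin REG4 (-3.39), RAB8B (-3.33) and IMPACT (-3.29). In 6 of the 12 falls (ZNF711, NPNT, NPTX2, SH3BGRL, REG4 and COL4A1) the mean on the arrays labelled HMGA2, and in 4 of the 12 rises (PRKCQ, PCOLCE2, PDE2A and GLMP) that on the arrays labelled vector, lay below 7.87 log2, the level used as the limit for dim genes, so the sizes and their order are uncertain there. The same holds for LFNG, FGFR3, SAA1 and DPP4 among the named list members. All 24 differences kept their direction and their side of the threshold under every alternative that was tallied by gene and measured it. The crossed block, the linear offset, every probe as the unit and the stricter thresholds were not tallied by gene. Chosen as the largest differences, the 24 had little room to lose a call. QPRT, S100A4, LCN2, KIT, CFTR and PBDC1, among others, rest on a single probe, so the mean of probes changes nothing there.

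**Figure D1:**
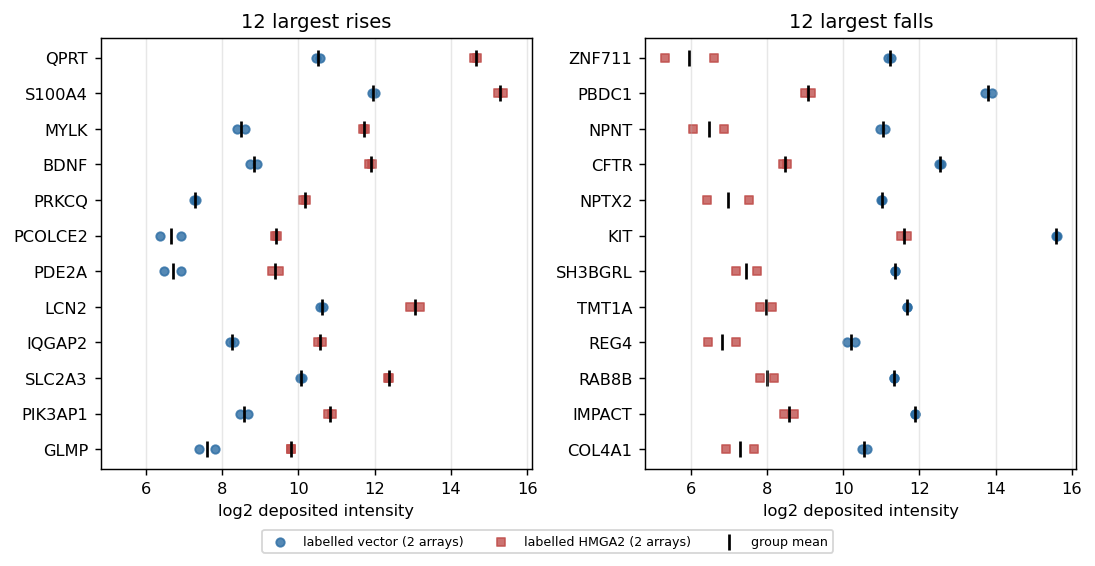
Log2 deposited intensity (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall. Circles are the 2 arrays labelled vector, squares the 2 labelled HMGA2 and vertical ticks the group means; in each gene both arrays of one group lie above both of the other, as for QPRT with a difference of 4.14.

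Of 13752 genes tested with limma, 5994 passed an adjusted p of 0.05. On the arrays labelled HMGA2, 2051 were higher and 3943 lower, so 34.2% of the calls were rises. That split depended on the scaling of the arrays: after quantile normalization 3844 genes were higher and 3114 lower, 55.2% rises, and the median over all genes moved by 0.18 log2, from -0.09 to 0.09. In both versions 2051 genes were called higher and 3018 lower, and 0 were called in opposite directions. Among differences of at least 2 log2, 17 genes were higher and 134 lower as deposited, and 29 were higher and 90 lower after quantile normalization. Before dim genes were left out, replicate arrays differed most at low levels: in the dimmest of 10 equal bins, whose genes were not tested, the median difference was 1.21 log2 between the vector arrays and -1.38 between the HMGA2 arrays. From bin 4 upward it was at most 0.21 in size.

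**Figure D2:**
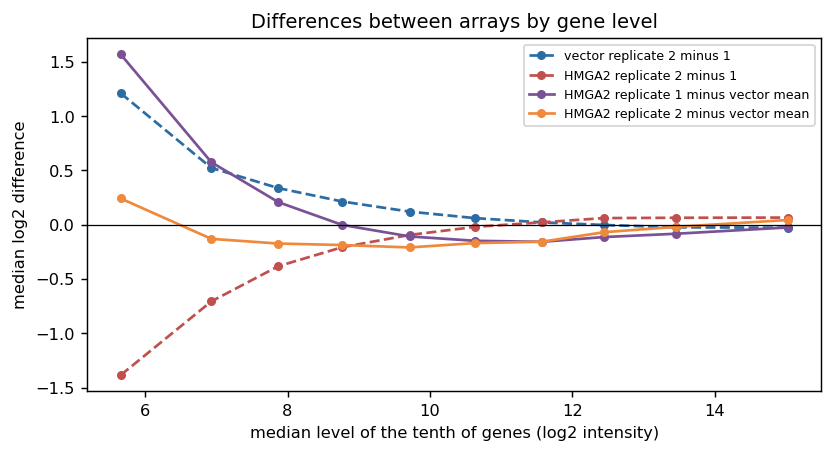
Median log2 difference (vertical axis) in 10 equal bins of all genes, dim ones included, ordered by their median log2 intensity (horizontal axis). Dashed lines compare the 2 arrays of one group and solid lines each HMGA2 array with the vector mean. The replicate arrays drift apart in the dimmest bin, which was not tested, by 1.21 and -1.38 log2. In bin 3, tested in part, they differ by 0.34 and -0.38.

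Of 37 gene lists fixed before the data were examined, cholesterol synthesis was the only 1 that passed limma's camera test in the main analysis. Of its 21 measured members 12 rose and 2 fell, against 12 and 3 adjusted over the list alone, with a median of 0.38 log2 (adjusted p = 0.00226). SQLE, which makes squalene epoxide, rose by 1.33 log2 (SE 0.08), the sterol isomerase gene EBP by 1.14 (SE 0.08), ACAT2 by 0.91 and the transcription factor SREBF2 by 0.89. The call held after quantile normalization, with 14 higher and 1 lower (adjusted p = 0.0326). The number of lists past the threshold was 4 without vector replicate 1, vector replicate 2 or HMGA2 replicate 1, and 3 with array medians subtracted or without the filter on dim genes. Wnt targets and histones, both lower, were added in each of these, stem cell markers (lower) without either vector replicate, and the unfolded protein response list (higher) without HMGA2 replicate 1. With the correlation within each list estimated from the data (0.048 for cholesterol synthesis), the cholesterol call was lost (camera adjusted p = 0.901), and no list passed. That form of camera takes its p-value from the 2 residual degrees of freedom, on which hardly any list could pass. It therefore cannot tell whether correlation within the list accounts for the call. The estimate of 0.048 lay above the preset of 0.01, so the camera p-values at the preset may be too small for this list.

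Stress and amino acid genes moved both ways. In the list of the unfolded protein response and ATF4 targets 14 of 31 members rose and 9 fell, against 16 and 9 adjusted over the list alone (camera adjusted p = 0.0673). CHAC1 rose by 1.17 log2 and the amino acid transporter SLC7A5 by 1.08, while EDEM1 (-1.56) and SEL1L (-1.19), which act in the clearing of misfolded proteins, fell. Of 15 heat shock genes 0 rose and 9 fell, and the same counts were found adjusted over the list alone, but after quantile normalization 4 rose and 5 fell. CRYAB (-1.33), HSPA2 (-1.06) and HSPA8 (-0.68) fell; DNAJB4 (-0.53) lost its call after quantile normalization. Among 22 targets of NRF2 and xenobiotic enzymes 6 rose and 7 fell, against 6 and 8 adjusted over the list alone. AKR1C3 (-2.69) and ALDH3A1 (-1.23) fell, and the subunits of glutamate-cysteine ligase went opposite ways, GCLM by -1.49 and GCLC by 1.32. In the metallothionein list 2 of 6 rose and 3 fell, also adjusted over the list alone, with MT1X at 0.80, MT3 at 0.43, MT2A at -0.30 and the zinc exporter SLC30A1 at -1.54.

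Changes among genes of the intestinal stem cell and Wnt programmes were mostly falls on the arrays labelled HMGA2, as were 3943 of the 5994 calls over all genes. No list in this paragraph passed camera in the main analysis, the adjusted p being 0.445 for Notch genes and 0.407 for TGF-beta and SMAD targets. Of 22 Wnt and beta-catenin targets 1 rose and 10 fell, against 1 and 11 adjusted over the list alone, and 4 rose and 10 fell after quantile normalization (camera adjusted p = 0.10 as deposited). The log2 difference was -2.77 (SE 0.17) for CD44, -2.0 (SE 0.08) for SOX4, -1.98 (SE 0.09) for SP5 and -1.88 (SE 0.13) for MYC. Among 13 stem cell markers 0 rose and 6 fell (camera adjusted p = 0.225 as deposited). The counts were 1 and 7 adjusted over the list alone and 1 and 6 after quantile normalization. CD24 (-3.22), ASCL2 (-1.46) and LGR5 (-1.45) fell. CD44, ASCL2 and LGR5 belong to both this list and the Wnt list, so their falls are counted in each. Of 14 Notch genes 1 rose and 7 fell in both counts, all genes and adjusted over the list alone, and 2 rose and 5 fell after quantile normalization, with NOTCH1 at -2.32, LFNG at -2.94 (below the limit for dim genes on the arrays labelled HMGA2), NOTCH3 at -0.83 and NRARP at -0.72. In the list of TGF-beta and SMAD targets 3 of 23 rose and 9 fell, against 3 and 10 adjusted over the list alone. ID1 (-2.33), TGFB1 (-1.95) and TGFBI (-1.15) fell, whereas THBS1 rose by 1.67. Of 19 YAP and TEAD targets 8 rose and 4 fell in both counts, among all genes and adjusted over the list alone; CRIM1 rose by 1.23 and CCN2 by 0.83, and MYOF (-1.66) and DLC1 (-1.26) fell.

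Differentiation genes followed no single direction. Among 20 goblet and enteroendocrine genes 0 rose and 7 fell, likewise adjusted over the list alone, though 3 rose and 5 fell after quantile normalization. AGR2, a protein disulfide isomerase of mucus-secreting cells, fell by 3.20 log2 (SE 0.11), and TFF3 (-1.35) and MUC13 (-1.14) fell less. In the enterocyte list 2 of 19 rose and 4 fell, also adjusted over the list alone, with 5 each way after quantile normalization; the microvillus protein VIL1 rose by 1.23 and DPP4, dim on the arrays labelled vector, by 1.02, and KRT20 fell by 2.74. Of 10 keratins 1 rose and 2 fell, also adjusted over the list alone, and 5 rose and 2 fell after quantile normalization. KRT8 fell by 2.43 and KRT14 rose by 0.33; the median of the list was 0.04 and its mean -0.44. Among 27 genes of epithelial adhesion and polarity 6 rose and 11 fell, against 7 and 11 adjusted over the list alone and 7 and 6 after quantile normalization. The desmosomal cadherin DSC2 fell by 2.13, and the tight junction genes CLDN1 (-1.17) and CGN (-0.86) and the polarity gene CRB3 (-1.17) fell too. Outside the rule for named genes, the 6 that rose were ST14 (0.73), CLDN4 (0.58), JUP (0.57), PKP2 (0.38), EPCAM (0.26) and CDH1 (0.26). These rises also passed after quantile normalization. Of 16 mesenchymal genes 2 rose and 2 fell, against 2 and 1 adjusted over the list alone and 4 and 1 after quantile normalization: S100A4 (3.33) and FN1 (1.53, SE 0.17) rose, TCF4 (-0.68) fell, and COL1A1 (-0.43) fell as deposited but lost its call after quantile normalization. Among 27 genes of matrix, proteases and integrins 11 rose and 7 fell, against 13 and 8 adjusted over the list alone and 15 and 5 after quantile normalization, with PLAU at 1.57, KLK6 at 1.45 and COL17A1 at -1.25 beside COL4A1 at -3.26.

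**Figure D3:**
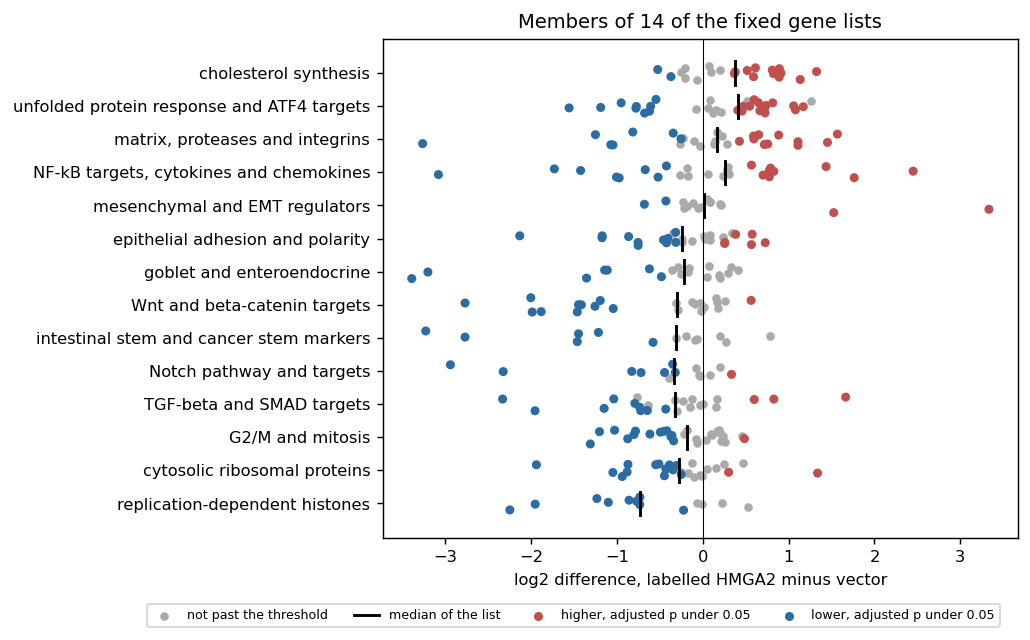
Log2 difference of each measured member (horizontal axis, labelled HMGA2 minus labelled vector) in 14 of the 37 gene lists. Red and blue points passed the threshold as higher and lower, grey points did not, and black bars are list medians, which run from 0.41 in the unfolded protein response list to -0.73 in the histone list.

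Cell cycle lists held both rises and falls, and neither phase list passed camera. Of 29 genes of G2/M and mitosis 1 rose and 13 fell, against 2 and 13 adjusted over the list alone and 7 and 12 after quantile normalization; the kinases TTK (-1.31) and CDK1 (-0.87) fell, as did ASPM (-1.20) and HMMR (-1.03). Of 29 genes of G1/S and DNA replication 7 rose and 6 fell in both counts, all genes and adjusted over the list alone, and 9 and 5 did so after quantile normalization, with CDC6 at 0.59, RFC4 at 0.57, POLA1 at -0.59 and E2F2 at -1.47. Their median was -0.09 while camera gave an upward direction. Among 26 CDK inhibitors and p53 targets 6 rose and 8 fell, also adjusted over the list alone, and 11 rose and 5 fell after quantile normalization. CDKN1C (-1.74), AEN (-1.16), DDB2 (-1.07) and CDKN1B (-0.83) fell. Outside the rule for named genes, the 6 that rose were PLK3 (0.82), SESN2 (0.65), SESN1 (0.61), CDKN1A (0.46), XPC (0.43) and SFN (0.34). For this list too camera pointed up while the median was -0.16. In the DNA repair list 5 of 23 rose and 6 fell, against 5 and 7 adjusted over the list alone and 6 and 3 after quantile normalization, with MGMT at -1.37, FANCI at -0.80, FANCA at 0.64 and APEX1 at 0.59. Of 13 replication-dependent histone genes 0 rose and 9 fell, also adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.10), and 2 rose and 8 fell after quantile normalization; H1-2 (-2.25), H2BC12 (-1.95), H2AC6 (-1.23) and H2BC5 (-1.10) fell.

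Inflammatory and growth factor genes also moved both ways. Of 26 NF-kB targets, cytokines and chemokines 9 rose and 8 fell, against 10 and 8 adjusted over the list alone: LCN2 rose by 2.45 log2 and SAA1, below the limit for dim genes on the arrays labelled vector, by 1.76, and the prostaglandin synthase PTGS2 (-3.08) and the cytokine IL33 (-1.73) fell. Among 23 interferon-stimulated genes 3 rose and 7 fell, also adjusted over the list alone, and 8 rose and 7 fell after quantile normalization. SAMD9 (-2.02), MX1 (-1.23) and HERC5 (-1.17) fell; OAS3 fell by 1.32 on its brightest probe, and the mean of its probes was 0.29 and not past the threshold. In antigen presentation 2 of 15 rose and 3 fell, also adjusted over the list alone, against 4 and 1 after quantile normalization, with PSMB10 at 1.00, TAP1 at 0.88, HLA-F at -0.47 and TAP2 at -0.51, a call that TAP2 lost after quantile normalization. Of 25 genes of EGFR, FGFR and MAPK feedback 7 rose and 10 fell, also adjusted over the list alone, and 9 rose and 7 fell after quantile normalization; the ligand gene EREG (-2.22), FGFR3 (-1.35, also dim on the arrays labelled HMGA2), SPRY2 (-1.22) and SPRED1 (-1.08) fell. Among 22 immediate early genes 5 rose and 4 fell, also adjusted over the list alone, against 12 and 4 after quantile normalization, with ATF3 at 1.06, JUNB at -1.68 and KLF4 at -1.21; the median of this list was 0.11 and its mean -0.09. In the BCL2 family and apoptosis list 6 of 21 rose and 6 fell, against 8 and 9 adjusted over the list alone and 8 and 3 after quantile normalization, with BIK at 1.05, CASP8 at -1.82, APAF1 at -1.43 and BIRC3 at -0.97.

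Metabolic and translation genes gave mixed counts. Of 28 genes of hypoxia and glycolysis 5 rose and 12 fell, also adjusted over the list alone, and 8 rose and 9 fell after quantile normalization. The fall reached BNIP3L at -1.80, HK1 at -1.62 and PGK1 at -1.11 log2, against the rise of SLC2A3. Among 21 genes of oxidative phosphorylation 2 rose and 7 fell, also adjusted over the list alone, with 5 each way after quantile normalization; UQCRB (-1.47), COX5A (-1.19), COX7C (-1.16) and NDUFB5 (-0.65) fell. Of 26 cytosolic ribosomal protein genes 2 rose and 13 fell, against 2 and 14 adjusted over the list alone (camera adjusted p = 0.282), and 4 rose and 9 fell after quantile normalization. RPL37 (-1.94), RPS6 (-1.05) and RPL34 (-0.94) fell, and RPS19 rose by 1.34. In the list of fluoropyrimidine metabolism and drug efflux 5 of 22 rose and 4 fell, against 6 and 4 adjusted over the list alone and 7 and 3 after quantile normalization: UPP1 (-1.51) and ABCC3 (-0.92) fell, and ABCC10 and UCK2 rose by 1.11 and 0.82.

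None of the developmental lists passed camera. The let-7 and HOX lists, both lower, were among the 18 of 37 lists that limma's fry called on the deposited values, the only ones it was run on. Their medians were -0.12 and -0.14 as deposited, against -0.09 over all genes. After quantile normalization both list medians were 0.03, so these fry calls may reflect the scaling of the arrays. Among 14 let-7 and oncofetal genes 2 rose and 5 fell, also adjusted over the list alone, against 4 and 5 after quantile normalization, with CDC25A at -1.48, H19 at -1.19, E2F5 at -1.10 and IGF2BP3 at -0.93. Of 25 HOX genes 2 rose and 6 fell, also adjusted over the list alone, against 4 and 6 after quantile normalization: HOXD9 at 1.32 and HOXC4 at 0.95, HOXA13 at -1.68 and HOXB6 at -0.93. In the cancer-testis list 0 of 7 rose and 2 fell, also adjusted over the list alone, PAGE1 (-0.81) and PAGE5 (-0.38), and PAGE5 lost its call after quantile normalization. Few markers of other cell types passed the threshold. For fibroblasts and endothelium 1 of 10 rose (ESAM, 0.38) and 1 fell (COL1A1), 0 passed adjusted over the list alone, and 4 rose and 0 fell after quantile normalization. For blood cells 2 of 14 rose (MS4A1 at 1.17, CD68 at 0.63) and 1 fell (CD14, -0.69), against 0 and 1 adjusted over the list alone and 4 and 1 after quantile normalization. For neuronal and other epithelial lineages 1 of 10 rose (NKX2-1, 0.69) and 1 fell (KLK3, -0.74), against 0 and 1 adjusted over the list alone and 3 and 2 after quantile normalization.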

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

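The direction counts depended on scaling, and the cause was not tested. Genes called higher numbered 3844 after quantile normalization, 3853 with normexp and quantile normalization (chosen after seeing the data) and 3715 with array medians subtracted, which left 2479 lower. Requiring at least 1 log2 left 1304 genes (180 higher, 1124 lower) and an adjusted p under 0.01 left 3727 (1037 higher), both smaller by construction. Testing every probe gave 9327 calls (6348 lower), with more features tested. The replicate block gave 5329 (1819 higher, 3510 lower). Same-numbered arrays correlated at -0.20 in their deviations, so the numbers were also crossed, which gave 7209 (2590 higher, 4619 lower). Crossing reverses the sign of that correlation by construction, so the larger number of calls is no independent check. Leaving out 1 array gave 5323 to 5525 calls, 1650 to 1969 higher and 3542 to 3673 lower, the lone array of a group being assumed to vary like the others.

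The fall of the brighter HMGA2 probe lost its call after quantile normalization (-0.19), normexp (-0.19), array medians (-0.17) and with the mean of probes (-0.0097), and ranged from -0.47 to -0.31 with 1 array left out, the call ending without vector replicate 1 (adjusted p = 0.0673) or HMGA2 replicate 1 (0.0627). The rise of the other probe lost its call after quantile normalization (0.59), normexp (0.59) and with no intensity trend (0.37), and ranged from 0.17 to 0.57, the call ending without the same arrays (adjusted p = 0.462 and 0.433). It kept its call with array medians, the robust model and the replicate block. The cause was not tested.

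Lists past the threshold numbered 3 with array medians, 3 without the filter, 0 with an estimated correlation, 18 with fry and 1 to 4 with 1 array left out; without vector replicate 1, vector replicate 2 or HMGA2 replicate 1 the number was 4. fry, run on the deposited values only, called DNA repair (adjusted p = 0.0332) and the BCL2 family (0.0380) lower where camera pointed up. It does not compare a list with other genes. Of 154 named genes 134 kept their direction and side of the threshold under every alternative that was tallied by gene and measured them. Another 19 lost the call under at least 1. The crossed block, the linear offset, every probe as the unit and the stricter thresholds were not tallied by gene. The filter at the 50th percentile measured only 108 of the named genes. OAS3 reversed with the mean of its probes (0.29). The replicate block ended the call of 6 named genes and of no list. Low signal over background limits the dimmest genes.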

Other observations

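The tests of the HMGA2 probes and of the X-linked genes were chosen after the result was seen. The relation with gene density was noticed while looking at neighbouring genes; the criteria for its tests were written before their values were computed.

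Further large falls on the arrays labelled HMGA2 lay outside the rule for named genes and were chosen after their values were seen. MGST1, a microsomal glutathione transferase, fell by 3.20 log2, from 6628 ± 291 (SD, n = 2) to 720 ± 7.07. SELENOP, the selenium transport protein, fell by 3.12. PDP1, a phosphatase that activates pyruvate dehydrogenase, fell by 3.18 and PLBD1 fell by 3.25. RPL14, a ribosomal protein gene, fell by 3.06, from 20086 ± 3290 to 2458 ± 825. HMGA1, the paralog of HMGA2, rose by 0.46 (SE 0.08, adjusted p = 0.00478).

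Probes of 1 gene did not always move together. Of 1180 genes with more than 1 probe past the threshold, 314 (26.6%) had probes in opposite directions, against a mean of 526 (487 to 565) in 100 shuffles of the directions. These counts took in dim probes, which the tests of genes and of unnamed probes left out. Of 3806 unnamed probes tested, 1048 passed, 289 higher and 759 lower.

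Genes in gene-poor regions were lower, relative to genes in gene-dense regions, on the arrays labelled HMGA2. A first search, over running medians of 15 neighbouring genes after quantile normalization, gave little: of 200 shuffles of the genes 17 held a median at least as low as the lowest (-0.86) and 9 at least as high as the highest (0.63). With genes then ranked by protein-coding genes within 1 Mb on each side, the densest of 5 equal bins exceeded the sparsest by 0.22 log2 over 13692 genes (shifted-position permutation p = 0.001, the smallest that 1000 shifts can give). Array background is argued against by the brighter genes, which gave 0.28, and gene length by the mean difference between dense and sparse genes within 5 bins of length, 0.126 against 0.157 overall. Replicate arrays of 1 line differed by 0.018 and -0.018, but variation between separately selected lines, base composition, RNA quality and probe position were not tested, and they and an effect of HMGA2, which binds AT-rich DNA, may all contribute.

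The direction of HMGA2 raises the question of swapped labels. A swap with probes that detect the plasmid predicts both probes higher on the arrays labelled vector, and the criterion against it, written after the result was seen, was a second probe higher on the arrays labelled HMGA2 and past the threshold. That was met as deposited (0.37, adjusted p = 0.0385), with array medians subtracted (0.59, adjusted p = 0.000365), the robust model (adjusted p = 0.00514) and the replicate block (0.0102), but not after quantile normalization (0.59, adjusted p = 0.0583), normexp (0.0532), without the intensity trend (0.371) or without vector replicate 1 or HMGA2 replicate 1 (0.462 and 0.433); the probe was higher on the arrays labelled HMGA2 in each. After the values were seen the decision was changed to require the quantile fit too, and since its arrays overlap (2728 and 3493 against 4596 and 3466), a swap and correct labels cannot be told apart here. Probes that miss the plasmid may also explain the result and were not tested, for lack of probe positions.

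Of 21 genes that fell by at least 3 log2, a limit chosen after the values were seen, 4 lie in a single stretch of the X chromosome: PBDC1, BRWD3, SH3BGRL and ZNF711. Of the 13 genes measured between PBDC1 and ZNF711, BRWD3 and SH3BGRL included, 2 fell by at least 2 log2, 2 (ATP7A at -1.10 and PGK1 at -1.11) changed by 1 to 2, and 9 changed by less than 1. A single deletion of the whole stretch is argued against by the 4 genes in it that lay above the median gene on the arrays labelled vector, of which 3 changed by less than 1 log2: COX7B (0.09), HMGN5 (0.16) and MAGT1 (-0.32). The level was first taken on the arrays labelled HMGA2, which the falls themselves can move. Separate small deletions, silencing, the relation with gene density and differences between the selected lines may remain, and were not tested.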
